A study of Mus musculus with 12 samples.

How the data were processed

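The data were 12 libraries, 1 per tumour, from 6 PDA.69 tumours of WT hosts and 6 of Alb-Cre Stat3f/f hosts. Per the labels, RNA was scraped from slides of fixed, paraffin-embedded tissue, isolated with an RNeasy FFPE kit and made into QuantSeq 3' mRNA-Seq FWD libraries (Lexogen), which yield reads near the 3' end of a transcript, so that counts do not scale with transcript length. The deposited values are counts per gene symbol that the authors made without normalisation: whole numbers with a different total in each library. The submitters' processing notes name STAR, an aligner, and the mouse genome build mm10; the versions, the counting tool, the gene annotation, the strand setting, the trimming and any filters are not given in the sources used here. No use of molecular identifiers is stated, so reads are not known to be independent molecules, and intervals cover counting error only. How reads shared between paralogs were counted is not given in the sources used here, which bears on Saa1 and Saa2, the H2 genes, Ly6c2, the Gbp genes and Hspa1a.

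The table held 24982 entries. Of these, 26 carried a date number in place of a gene symbol, and were left out, since the genes behind them cannot be told; they held 0.0690 to 0.166% of a library's counts. The remaining 24956 symbols were matched to GENCODE release M21 (GRCm38, the same assembly as mm10), and 24420 (97.9%) matched 1 gene. No mitochondrially encoded gene was among them, so a mitochondrial share was not analysed here. Library totals ran from 5691707 to 8085609 counts. All 12 libraries were used. The labels give no batch, date, host sex or pairing. The numbers that start the sample descriptions are lower for every Alb-Cre Stat3f/f tumour than for any WT tumour. What they count is not given, and an order that follows the genotype cannot be told apart from it. No pair of libraries of 1 genotype was close enough in its counts to be 1 library sequenced again (chi-square per gene of at least 12.6). Pairs across genotypes were not compared.

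Gene counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the genotype as group (minimum count 10, minimum total count 15, large-group proportion 0.7), which left 12856. Libraries were scaled by TMM (factors 0.578 to 1.29). Genotypes were compared by the robust quasi-likelihood test with genotype as the sole term, two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as the threshold. The common dispersion was 0.0626, a biological coefficient of variation of 0.250. CPM values are TMM-normalised, and fold changes are Alb-Cre Stat3f/f over WT with the SE of the fit.

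The test, the 36 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. A list was scored in each tumour as the mean log2 CPM (prior count 2) of its members that passed the filter, and lists with at least 3 such members were compared by an exact two-sided permutation test over all 924 relabellings, with Benjamini-Hochberg adjustment over 32 lists. The tumour was the unit because list members vary together between tumours. Lists were also tested by camera from limma 3.58.1, with a preset correlation of 0.01 and with the correlation estimated per list, and by fry. The preset camera called 20 lists, the estimated camera 2 and fry 16. The lists of natural killer, skeletal muscle, erythroid and mitochondrially encoded genes had fewer than 3 tested members and no score. Correlations between scores used permutation of 1 score, exact within a genotype and 100000 draws over the 12 tumours.

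Genes were named by rule: in each direction the 15 largest fold changes among genes past the threshold with a higher group mean of at least 5 CPM, predicted genes skipped; in each list described, up to 4 members past the threshold adjusted over the list alone, or the 2 with the smallest p where there were none; and, whatever their values, Stat3, Alb, Saa1, Saa2, Saa3, Tlr2, Cd3e, Cd4, Cd8a, Foxp3, Gzmb, Ifng, Cd274 and Krt19. The text names part of the genes so chosen, mainly those whose call did not rest on a single tumour. Of the genes so chosen, 1 is not reported here. The acinar genes Cpa1 and Cela1 and the members of 3 further lists (glucocorticoid response, alternatively activated macrophages and Y chromosome) were named after their values were seen.

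The pipeline was tested on simulated counts with the same means, dispersions and group sizes. The genes to change were drawn only from those with a mean of at least 5 CPM. Recovery of genes with lower means, such as Klrd1, was therefore not measured. Of genes changed 1.5-fold, 33 of 67 (49.3%) were recovered, of those changed 2-fold 56 of 67 (83.6%), and of those changed 3-fold 66 of 66. There were 3 false calls, 1.80% of calls. Of the 32 lists, 3 raised 1.5-fold were called and 0 others. Genes were drawn independently, with no shared variation in cell content between tumours. The simulation therefore does not measure recovery or false calls of lists or genes that vary together, as they do in these tumours. At this depth and spread many 1.5-fold changes would go uncalled, so a gene that did not pass is not shown to be equal.

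Alternatives were RLE and upper quartile factors, no filter, a strict filter (at least 10 CPM in 6 tumours), DESeq2 1.42.0, limma voom with quality weights, edgeR without robust estimation, the replicate number as a block, log10 library size or the number of genes detected as a covariate, libraries thinned to the smallest total, other list scores and tests, and each tumour left out in turn. After seeing how much acinar content varied, 3 more were added: the acinar score as a covariate, the acinar genes and the ribosomal RNA gene Rn45s left out, and the 5 tumours with over 15% acinar counts left out. The covariate fit takes the part of each value that follows the acinar score out of the genotype difference. For list scores its p came from relabelling the residuals of the score on the acinar score in every way. This residual permutation is approximate, not exact.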

Results

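RNA abundance was measured in 12 tumours grown from PDA.69, a pancreatic ductal adenocarcinoma cell line derived from KPC mice, a genetically engineered model of pancreatic cancer, and labelled as low in T cells. Of the tumours, 6 grew in wild-type (WT) host mice and 6 in Alb-Cre+/+ Stat3f/f host mice. In the latter the albumin promoter drives Cre, and Stat3, a transcription factor downstream of interleukin 6, is removed from hepatocytes. RNA was scraped from fixed, paraffin-embedded sections and made into libraries that read the 3' ends of polyadenylated transcripts. The libraries held 5691707 to 8085609 counts each, up to 7594880 in WT and from 6083638 in Alb-Cre Stat3f/f tumours. Between 15221 and 16688 genes had a count in a tumour. The p-values measure the spread between these samples, since the labels do not state that each tumour came from a separate mouse.

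The tumours differed in how much normal exocrine pancreas they held. The 15 acinar genes, which encode digestive enzymes of the pancreas such as Prss2, Cpa1 and Cela1, took 5.87 ± 6.68% of counts in WT and 20.6 ± 12.98% in Alb-Cre Stat3f/f tumours (SD, n = 6 each). The exact two-sided permutation p was 0.0325, and 0.0693 after Benjamini-Hochberg adjustment over 8 library measures. The share was over 15% in 5 tumours, namely WT 5 and Alb-Cre Stat3f/f 1, 2, 3 and 4, and was 0.705% in Alb-Cre Stat3f/f 5. The first principal component carried 62.1% of the variance of the 500 most variable genes (exact permutation p = 0.0346 between genotypes, adjusted p = 0.0693) and the next 7.30% (exact permutation p = 0.0476, adjusted p = 0.0762). The first component had Pearson r = 0.965 with the acinar score, so it mainly followed acinar content. For the next component r was 0.121. The 50 most abundant genes took 23.7 ± 7.22% of WT counts and 41.9 ± 16.2% of Alb-Cre Stat3f/f counts (exact permutation p = 0.0325, adjusted p = 0.0693). Totals had an exact permutation p of 0.223, genes detected 0.141 and the share of the ribosomal RNA gene Rn45s 0.764.

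**Figure D1:**
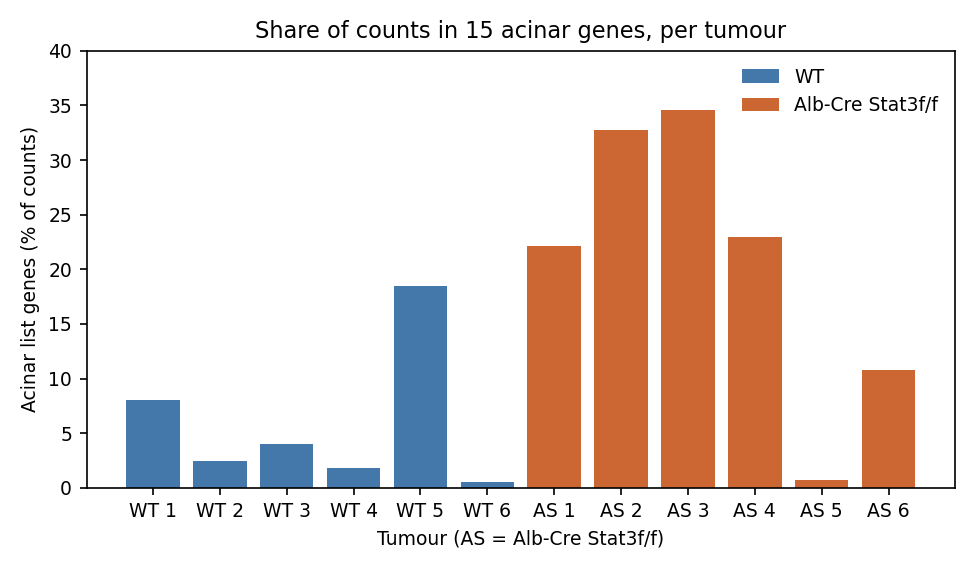
Bars give the percent of each library's counts in the 15 acinar genes, for 6 WT and 6 Alb-Cre Stat3f/f (AS) tumours. Shares ran from 0.495% to 18.4% in WT and from 0.705% to 34.6% in Alb-Cre Stat3f/f tumours.

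The comparison of the hosts addressed what hepatocyte Stat3 and the serum amyloid A proteins, which the liver makes in the acute phase response, have to do with immune cells in the tumour. Stat3 itself (chromosome 11, 100885098 to 100939540, minus strand, GRCm38) had 258 ± 34.0 CPM (counts scaled to library size) in Alb-Cre Stat3f/f and 257 ± 15.5 in WT tumours (SD, n = 6). Its log2 fold change was 0.00 ± 0.10 (SE) with an adjusted p of 0.996 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2 of 6 Alb-Cre Stat3f/f tumours lay above every WT tumour. The gene was deleted in the host liver and not in the tumour line, and a 3' tag need not lie in the deleted part, so the value does not bear on the deletion. Among the acute phase genes, Saa1 and Saa2 (chromosome 7) had few counts. Saa1 had 227 counts in WT and 24 in Alb-Cre Stat3f/f tumours, a WT to Alb-Cre Stat3f/f ratio of 7.62 (95% exact binomial interval 4.99 to 12.1, counting error only). It did not pass the low count filter and so was not in the main test. WT 4 held 119 of the WT counts, and without it the Saa1 ratio was 4.44 (2.83 to 7.23). Saa2 had a log2 fold change of -2.32 ± 0.83 and an adjusted p of 0.145 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 4 of 6 tumours below every WT tumour. Saa1 and Saa2 are close paralogs whose reads can be shared. Saa3, which is made outside the liver, had a log2 fold change of 0.54 ± 0.32, and Tlr2, a receptor for serum amyloid A, 0.44 ± 0.32. Alb had 76.9 ± 50.6 CPM in Alb-Cre Stat3f/f and 64.2 ± 47.8 in WT tumours. Of the 8 acute phase genes tested 5 had a positive and 3 a negative fold change, 0 passed over all genes and 0 adjusted over the list alone. Their score differed by 0.15, with an exact permutation adjusted p of 0.649 and 2 of 6 tumours above every WT tumour. The sign of that difference was not stable. It was -0.24 without a filter, -0.09 with the acinar score as a covariate, -0.11 without the acinar genes and Rn45s, and -0.72 without the acinar-rich tumours. It was also negative without WT 5, WT 6 or any 1 Alb-Cre Stat3f/f tumour, down to -0.22 without Alb-Cre Stat3f/f 3. In each such fit the low count filter and scaling were run anew, so the members scored could change. With the main scores of the tumours left, the difference stayed positive without WT 5 or any 1 Alb-Cre Stat3f/f tumour. The sign changes in those settings therefore do not rest on the tumour left out alone. With thinned counts the score difference was 0.43.

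In tumours of Alb-Cre Stat3f/f hosts, genes of T cells, cytotoxic lymphocytes, dendritic cells, monocytes and macrophages were higher than in WT hosts. Genes of antigen presentation and of the interferon response were higher with them, with MHC class I genes about 2.04-fold higher on average. Genes of hypoxia and glycolysis fell by 0.59 on the log2 scale on average, and the scores of fibroblast, endothelial and pericyte markers did not pass. Of 36 gene lists, 32 had at least 3 members tested and 16 differed between genotypes by an exact two-sided permutation test of the mean log2 CPM of their members, 13 higher and 3 lower in Alb-Cre Stat3f/f tumours. The smallest p that the 924 relabellings can give is 0.0022. Of these 16, the monocyte and MHC class I lists also passed camera with an estimated correlation. Without the 5 tumours with over 15% acinar counts, 5 WT and 2 Alb-Cre Stat3f/f tumours were left, whose 21 relabellings give no p under 0.048, and 0 lists passed.

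**Figure D2:**
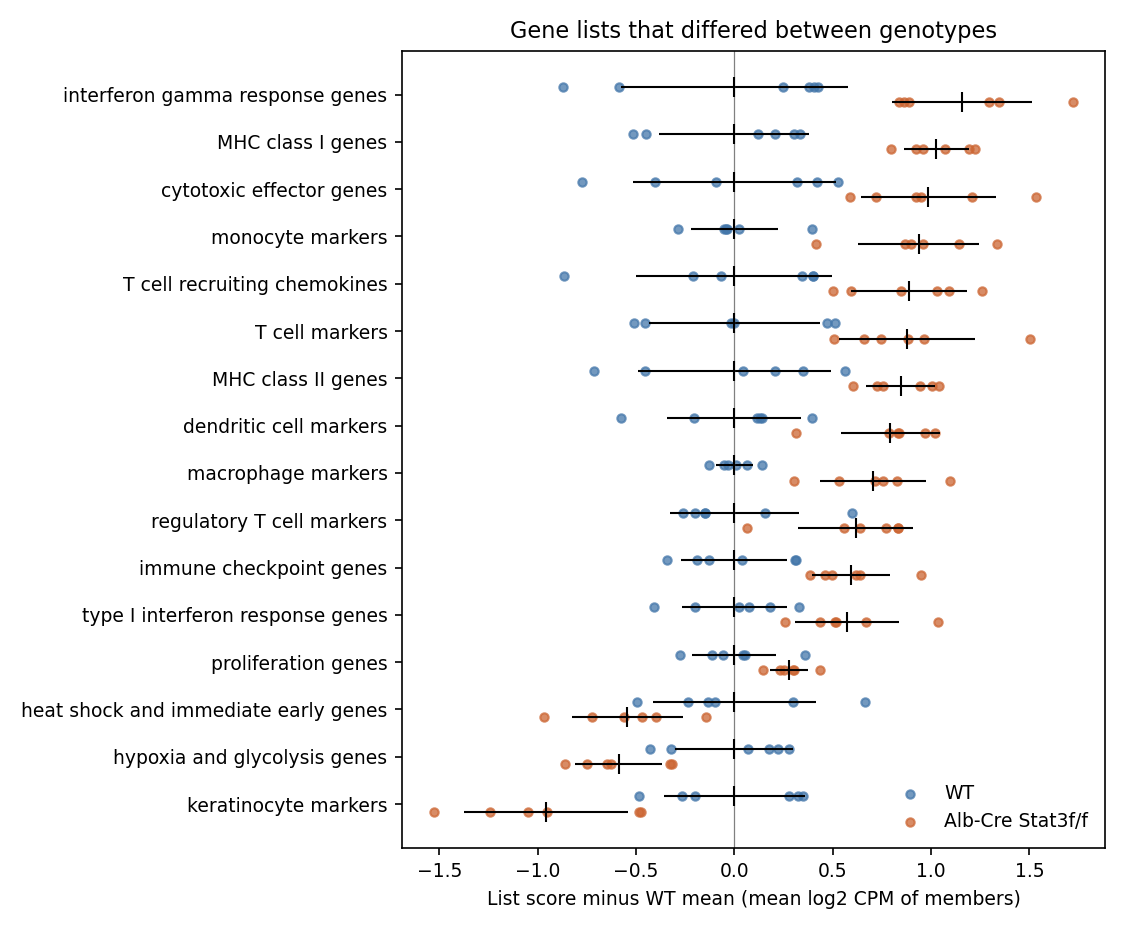
Points give each tumour's score (mean log2 CPM of the members) minus the WT mean for the 16 lists that differed, with bars at the mean and SD of 6 tumours per genotype. In 8 of the 13 higher lists every Alb-Cre Stat3f/f tumour lay above every WT tumour.

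Over 12856 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 287 genes higher and 96 lower in Alb-Cre Stat3f/f tumours, and 2490 genes had an unadjusted p under 0.05. With the acinar score as a covariate 135 genes were higher and 34 lower, and of the original calls 121 and 29 remained. Without the 5 acinar-rich tumours 83 were higher and 14 lower. The number of higher genes was 187 without WT 1, 169 without WT 3, 182 without WT 4, 157 without WT 6, 141 without Alb-Cre Stat3f/f 1, 186 without Alb-Cre Stat3f/f 2 and 471 without Alb-Cre Stat3f/f 5. The number of lower genes was 57, 45, 63, 152 and 63 without WT 1, 3, 4, 5 and 6 in turn, and 37, 52, 60, 197 and 222 without Alb-Cre Stat3f/f 1, 2, 3, 4 and 5.

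T cell markers were higher in tumours of Alb-Cre Stat3f/f hosts, at a mean log2 CPM of 2.64 ± 0.35 against 1.77 ± 0.44 in WT (SD, n = 6). All 15 tested members had a positive fold change. Over all genes 1 of them rose, Cd247 (the zeta chain of the T cell receptor complex), 0 fell and 14 did not pass, and 8 rose adjusted over the list alone. The difference of 0.88 had an exact permutation adjusted p of 0.0115, with 5 of 6 tumours above every WT tumour, and an adjusted p = 0.101 with an estimated correlation. With the acinar score as a covariate it was 0.94. Cd3e, a subunit of the T cell receptor complex, had a log2 fold change of 1.09 ± 0.35 and Cd4 1.02 ± 0.35. Cd8a, the co-receptor of cytotoxic T cells, had 10.3 ± 4.70 CPM against 4.10 ± 2.37, a log2 fold change of 1.34 ± 0.39. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0954 for Cd3e, 0.109 for Cd4 and 0.0698 for Cd8a, with 2, 3 and 5 of 6 tumours above every WT tumour. Cd3e passed that edgeR test without WT 2 (adjusted p 0.0256), and Cd8a without WT 2 (0.0480) or Alb-Cre Stat3f/f 3 (0.0387). Cd247 rose by 1.42 ± 0.35 on the log2 scale (adjusted p = 0.0283 by the same edgeR test, 6 of 6 tumours). Its edgeR Benjamini-Hochberg adjusted p was 0.068, 0.069 and 0.069 without WT 1, 3 and 6, 0.059, 0.077 and 0.058 without Alb-Cre Stat3f/f 1, 2 and 6, and 0.0914 with the acinar score as a covariate, where Cd247 rose by 1.38 ± 0.39. The fold was nearly kept and its SE was wider.

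Cytotoxic effector genes, the granule and receptor genes of killer lymphocytes, were higher by 0.99 (exact permutation adjusted p = 0.00866, 6 of 6 tumours above every WT tumour; adjusted p = 0.0920 with an estimated correlation), and by 0.91 with the acinar score as a covariate. All 8 tested members had a positive fold change, of which 2 rose, 0 fell and 6 did not pass over all genes, and 4 rose adjusted over the list alone. Nkg7, a granule protein, rose from 7.81 ± 2.73 to 19.2 ± 6.37 CPM (log2 fold change 1.31 ± 0.24, adjusted p = 0.00538 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 of 6 tumours). Klrd1, a receptor of natural killer and cytotoxic T cells, rose from 1.17 ± 0.896 to 4.59 ± 1.37 CPM (log2 fold change 1.99 ± 0.41, adjusted p = 0.0124 by the same edgeR test with Benjamini-Hochberg adjustment, 6 of 6 tumours). Gzmb, encoding granzyme B, had 34 counts in Alb-Cre Stat3f/f and 4 in WT tumours, a ratio of 10.6 (95% exact binomial interval 3.76 to 40.9, counting error only). It did not pass the low count filter and so was not in the main test. WT 1 held 3 of the 4 WT counts, and without it the Gzmb ratio was 34.1 (5.72 to 1387). Ifng, with 21 and 11 counts, and Foxp3, with 11 and 16, did not pass that filter either. Of the natural killer markers only Klrc1 and Il18rap were tested, with log2 fold changes of 0.02 and -0.04.

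Immune checkpoint genes were higher by 0.59 (exact permutation adjusted p = 0.00866, 6 of 6 tumours above every WT tumour; adjusted p = 0.0867 with an estimated correlation), and by 0.54 with the acinar score as a covariate. Of 8 tested members 7 had a positive fold change and 0 passed over all genes, while 4 rose adjusted over the list alone, among them Pdcd1 (PD-1, log2 fold change 1.23) and Pdcd1lg2 (PD-L2, 1.34). Pdcd1 passed the edgeR test over all genes without WT 2, WT 5 or Alb-Cre Stat3f/f 4 (Benjamini-Hochberg adjusted p = 0.034, 0.046 and 0.032), and Pdcd1lg2 without WT 5 or Alb-Cre Stat3f/f 4 (0.048 and 0.039). Cd274, encoding PD-L1, had a log2 fold change of 0.54 ± 0.26. With only genes of at least 10 CPM in 6 tumours the checkpoint difference was 0.21 with an exact permutation adjusted p of 0.272. Regulatory T cell markers were higher by 0.62 (exact permutation adjusted p = 0.0297, 4 of 6 tumours above every WT tumour; adjusted p = 0.105 with an estimated correlation), and by 0.72 with the acinar score as a covariate. Of the 8 regulatory T cell markers 5 were tested, all with a positive fold change. Over all genes 0 passed, and 2 rose adjusted over the list alone, namely Tnfrsf18 (1.09) and Tnfrsf4 (0.81). Foxp3, the gene that defines these cells, did not pass the low count filter and had no part in the score. Its few counts, given above, were fewer in Alb-Cre Stat3f/f than in WT tumours. The score therefore does not show a rise of regulatory T cells. The exact permutation adjusted p of the regulatory T cell list was 0.0594 without WT 1, 0.0530 without WT 3, and 0.0554 without WT 6 or Alb-Cre Stat3f/f 1, 5 or 6.

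Macrophage markers were higher in all 6 Alb-Cre Stat3f/f tumours than in any WT tumour, with a score difference of 0.71 (exact permutation adjusted p = 0.00866; adjusted p = 0.0644 with an estimated correlation) and 0.67 with the acinar score as a covariate. All 14 members had a positive fold change, of which 7 rose, 0 fell and 7 did not pass over all genes, and 13 rose adjusted over the list alone. Mertk, a receptor for the uptake of dying cells, rose from 26.3 ± 5.05 to 51.7 ± 11.9 CPM, a log2 fold change of 0.97 ± 0.15. C1qb, a complement subunit, rose from 190.0 ± 28.1 to 289 ± 41.1 CPM, a log2 fold change of 0.60 ± 0.11. Monocyte markers were higher by 0.94 (exact permutation adjusted p = 0.00866, 6 of 6 tumours above every WT tumour; adjusted p = 0.0426 with an estimated correlation) and by 0.85 with the acinar score as a covariate. All 8 had a positive fold change, of which 3 rose, 0 fell and 5 did not pass over all genes, and 5 rose adjusted over the list alone. Ly6c2, a surface marker of inflammatory monocytes with a close paralog, rose by 1.77 ± 0.30 and Ccr2, their chemokine receptor, by 1.29 ± 0.25 on the log2 scale. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.00176 for Mertk, 0.00714 for C1qb, 0.00281 for Ly6c2 and 0.0143 for Ccr2, with 6, 6, 6 and 5 of 6 tumours above every WT tumour.

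Dendritic cell markers were higher by 0.79 (exact permutation adjusted p = 0.0115, 5 of 6 tumours above every WT tumour; adjusted p = 0.0792 with an estimated correlation), and by 0.75 with the acinar score as a covariate. Of 13 tested members 12 had a positive fold change, 4 rose, 0 fell and 9 did not pass over all genes, and 8 rose adjusted over the list alone. Wdfy4, needed for cross-presentation by type 1 conventional dendritic cells, rose from 14.5 ± 3.15 to 34.8 ± 7.84 CPM, a log2 fold change of 1.26 ± 0.18. Irf8, a transcription factor of the same cells, rose from 64.6 ± 15.7 to 110.5 ± 21.2 CPM, a log2 fold change of 0.78 ± 0.16. The adjusted p was 0.000686 for Wdfy4 and 0.0117 for Irf8 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 6 and 5 of 6 tumours above every WT tumour. Without the acinar-rich tumours Irf8 had a log2 fold change of 0.79 ± 0.21 and an edgeR Benjamini-Hochberg adjusted p of 0.134.

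MHC class I genes, which present peptides to CD8 T cells, had the most members past the test. All 12 tested members had a positive fold change, of which 9 rose, 0 fell and 3 did not pass over all genes, and 12 rose adjusted over the list alone. The score rose by 1.03, from 6.49 ± 0.38 to 7.52 ± 0.17 (SD, n = 6; exact permutation adjusted p = 0.00866, 6 of 6 tumours above every WT tumour; adjusted p = 0.0426 with an estimated correlation), and by 0.94 with the acinar score as a covariate. Psmb10, a catalytic subunit of the immunoproteasome, rose from 58.5 ± 10.97 to 129 ± 21.3 CPM, a log2 fold change of 1.14 ± 0.14. H2-K1 and H2-D1, the classical class I heavy chains, rose by 0.83 ± 0.14 and 0.74 ± 0.13 on the log2 scale, and reads of these paralogs can be shared. The adjusted p was 0.000170 for Psmb10, 0.00334 for H2-K1 and 0.00508 for H2-D1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, each with 6 of 6 tumours above every WT tumour. Without the acinar-rich tumours the edgeR Benjamini-Hochberg adjusted p of H2-D1 was 0.0913 at a larger log2 fold change of 0.86 ± 0.21, with fewer tumours and a wider SE. MHC class II genes were higher by 0.85 (exact permutation adjusted p = 0.00866, 6 of 6 tumours above every WT tumour; adjusted p = 0.0867 with an estimated correlation) and by 0.92 with the acinar score as a covariate. All 10 tested members had a positive fold change, of which 2 rose, 0 fell and 8 did not pass over all genes, and 9 rose adjusted over the list alone. Ctss, the protease that trims the invariant chain, rose from 292 ± 45.1 to 469.6 ± 60.6 CPM (log2 fold change 0.69 ± 0.12, adjusted p = 0.00308 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 of 6 tumours). The class II chain gene H2-Aa and Ciita, the class II transactivator, did not pass that test over all genes. With the acinar score as a covariate the edgeR Benjamini-Hochberg adjusted p was 0.181 for H2-Aa (log2 fold change 0.89 ± 0.27) and 0.0478 for Ciita (0.97 ± 0.24).

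Interferon gamma response genes had a score difference of 1.16 (exact permutation adjusted p = 0.00866, 6 of 6 tumours above every WT tumour; adjusted p = 0.0827 with an estimated correlation), and 1.15 with the acinar score as a covariate. All 15 members had a positive fold change, of which 5 rose, 0 fell and 10 did not pass over all genes, and 13 rose adjusted over the list alone. Gbp4, an interferon-induced GTPase, rose from 6.33 ± 2.21 to 24.5 ± 10.6 CPM, a log2 fold change of 1.96 ± 0.28. Irgm1, an immunity-related GTPase, rose from 8.76 ± 1.81 to 21.4 ± 2.86 CPM, a log2 fold change of 1.28 ± 0.17. The adjusted p was 0.00127 for Gbp4 and 0.000499 for Irgm1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, each with 6 of 6 tumours above every WT tumour. Type I interferon response genes were higher by 0.57 (exact permutation adjusted p = 0.0115, 5 of 6 tumours above every WT tumour; adjusted p = 0.102 with an estimated correlation) and by 0.58 with the acinar score as a covariate. Of 19 tested members 18 had a positive fold change, 1 rose (Rtp4), 0 fell and 18 did not pass over all genes, and 14 rose adjusted over the list alone. The edgeR Benjamini-Hochberg adjusted p of Rtp4 was 0.0232 (log2 fold change 0.66 ± 0.15, 6 of 6 tumours), 0.058 without WT 1, 0.051, 0.052 and 0.061 without Alb-Cre Stat3f/f 1, 3 and 6, and 0.102 with the acinar score as a covariate (0.54 ± 0.16). T cell recruiting chemokines were higher by 0.89 (exact permutation adjusted p = 0.00866, 6 of 6 tumours above every WT tumour; adjusted p = 0.101 with an estimated correlation) and by 0.77 with the acinar score as a covariate. Of 10 tested members 9 had a positive fold change, 1 rose, 0 fell and 9 did not pass over all genes, and 5 rose adjusted over the list alone. Cxcl10, a ligand of Cxcr3, rose from 5.61 ± 0.530 to 12.7 ± 6.48 CPM (log2 fold change 1.19 ± 0.26, adjusted p = 0.0172 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 of 6 tumours). Without Alb-Cre Stat3f/f 1 its edgeR Benjamini-Hochberg adjusted p was 0.051. Cxcl9, a ligand of the same receptor, had 177 ± 88.0 against 64.3 ± 32.9 CPM, with an adjusted p of 0.101 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 6 of 6 tumours above every WT tumour.

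**Figure D3:**
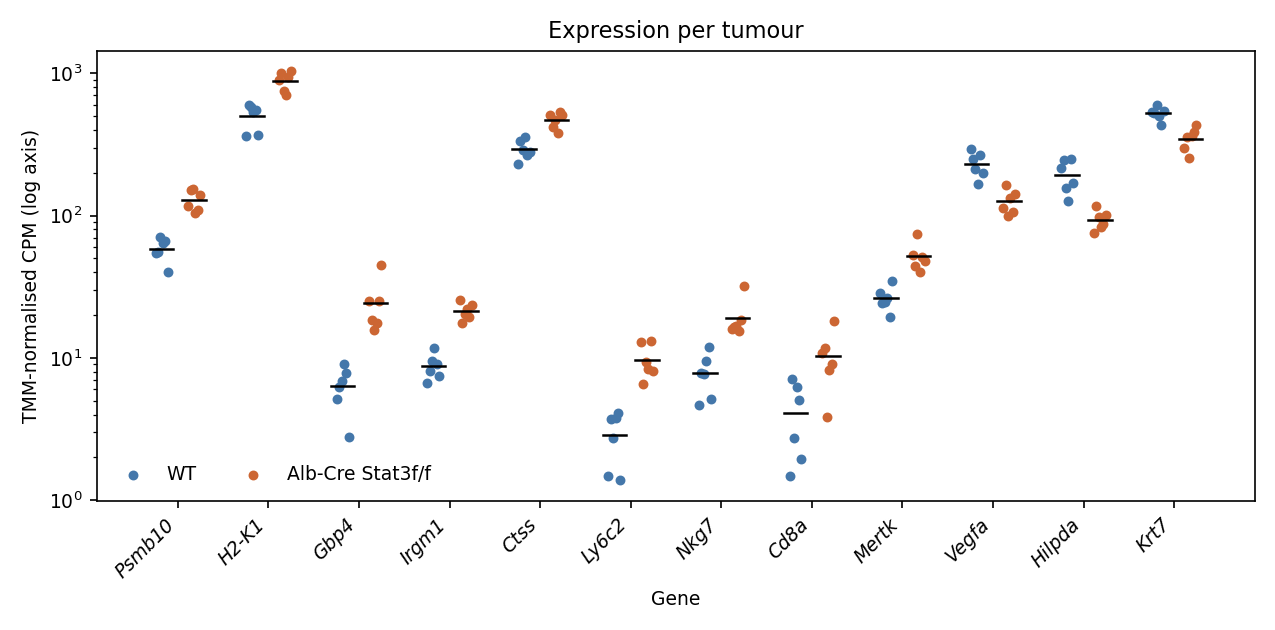
Points give TMM-normalised CPM on a log axis for 12 genes in 6 WT and 6 Alb-Cre Stat3f/f tumours, with lines at the means. Psmb10, Gbp4 and Nkg7 were higher in every Alb-Cre Stat3f/f tumour than in any WT tumour, and Vegfa and Hilpda were lower in every one.

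Hypoxia and glycolysis genes were lower in Alb-Cre Stat3f/f tumours, with a score difference of -0.59 (exact permutation adjusted p = 0.0266, 4 of 6 tumours below every WT tumour; adjusted p = 0.0867 with an estimated correlation) and -0.68 with the acinar score as a covariate. All 15 tested members had a negative fold change, of which 3 fell, 0 rose and 12 did not pass over all genes, and 10 fell adjusted over the list alone. Vegfa, encoding the main angiogenic growth factor, fell from 231 ± 46.3 to 126 ± 24.1 CPM, a log2 fold change of -0.87 ± 0.14. Hilpda, a lipid droplet protein induced by hypoxia that is outside the list, fell from 194 ± 50.8 to 93.6 ± 14.7 CPM, a log2 fold change of -1.05 ± 0.16. The adjusted p was 0.00233 for Vegfa and 0.00173 for Hilpda in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, each with 6 of 6 tumours below every WT tumour. Without the acinar-rich tumours the edgeR Benjamini-Hochberg adjusted p was 0.0867 for Vegfa and 0.0946 for Hilpda, at log2 fold changes of -0.85 ± 0.20 and -0.95 ± 0.23. Scored by the median over members, the hypoxia difference was -0.45 with an exact permutation adjusted p of 0.104. Without the acinar-rich tumours the mean score differed by -0.43, with an exact permutation adjusted p of 0.349.

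Heat shock and immediate early genes were lower by a score difference of -0.54 (exact permutation adjusted p = 0.0476, 3 of 6 tumours below every WT tumour; adjusted p = 0.183 with an estimated correlation) and -0.67 with the acinar score as a covariate. Of 12 members 10 had a negative fold change, 1 fell, 0 rose and 11 did not pass over all genes, and 3 fell adjusted over the list alone. Egr1, an immediate early transcription factor, fell from 106 ± 41.4 to 53.0 ± 9.68 CPM (a 2.01-fold fall, adjusted p = 0.0361 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 of 6 tumours below every WT tumour). Its edgeR Benjamini-Hochberg adjusted p was 0.068 and 0.062 without WT 1 and 2, 0.086, 0.094, 0.056 and 0.057 without Alb-Cre Stat3f/f 1, 3, 4 and 6, and 0.202 with the acinar score as a covariate (log2 fold change -0.91 ± 0.29). Hspa1a, an inducible heat shock protein with a close paralog, had 9.04 ± 3.75 against 34.8 ± 27.5 CPM, and its adjusted p was 0.0717 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 5 of 6 tumours below every WT tumour. The exact permutation adjusted p of the list was 0.0736 without WT 1 or WT 2, 0.0530 without WT 3, and 0.0554 without WT 6 or Alb-Cre Stat3f/f 1. It was 0.0823, 0.0909, 0.0774 and 0.0563 without Alb-Cre Stat3f/f 3, 4, 5 and 6. By the median over members, by members scaled to unit SD and by fry the adjusted p of the heat shock list was 0.157, 0.0570 and 0.0616 (exact permutation for the scores).

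Among epithelial genes, Sox9, a ductal transcription factor, fell from 926 ± 70.6 to 661 ± 65.8 CPM and Krt7, a ductal keratin, from 522 ± 54.4 to 348 ± 63.0 CPM, log2 fold changes of -0.49 ± 0.10 and -0.59 ± 0.12. The adjusted p was 0.0103 for Sox9 and 0.0113 for Krt7 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, each with 6 of 6 tumours below every WT tumour. With the acinar score as a covariate the edgeR Benjamini-Hochberg adjusted p was 0.0274 for Sox9 and 0.0515 for Krt7, and without the acinar-rich tumours that of Sox9 was 0.16 and that of Krt7 0.230. The log2 fold changes with the covariate were -0.47 ± 0.11 for Sox9 and -0.48 ± 0.12 for Krt7. Without the acinar-rich tumours they were -0.47 ± 0.14 and -0.40 ± 0.13, so Sox9 kept its fold with a wider SE and that of Krt7 was smaller. Krt19, another ductal keratin, had a log2 fold change of -0.13 ± 0.09. Of the 16 tested ductal epithelial markers 13 had a negative fold change, 3 fell, 0 rose and 13 did not pass over all genes, and 6 fell and 2 rose adjusted over the list alone. The epithelial score differed by -0.14 (exact permutation adjusted p = 0.284, 2 of 6 tumours below every WT tumour). It passed as lower with members scaled to unit SD (exact permutation adjusted p = 0.0416), by camera with the preset correlation (adjusted p = 0.000599) and by fry (adjusted p = 0.0169), so a fall of the epithelial list depended on the test. Keratinocyte markers, of which 3 were tested, had a score difference of -0.96 (exact permutation adjusted p = 0.0115, 5 of 6 tumours below every WT tumour; adjusted p = 0.0867 with an estimated correlation) and -0.73 with the acinar score as a covariate. All 3 had a negative fold change, of which 1 fell, 0 rose and 2 did not pass over all genes, and 2 fell adjusted over the list alone. Krt14, a basal keratin, fell from 16.2 ± 8.57 to 5.23 ± 2.93 CPM (log2 fold change -1.62 ± 0.41, adjusted p = 0.0473 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 of 6 tumours below every WT tumour). Its edgeR Benjamini-Hochberg adjusted p was 0.086, 0.083, 0.064 and 0.084 without WT 1, 3, 4 and 6, 0.11, 0.064, 0.066, 0.071 and 0.091 without Alb-Cre Stat3f/f 1, 2, 3, 4 and 6, and 0.146 with the acinar score as a covariate (log2 fold change -1.33 ± 0.40).

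Proliferation genes were higher by 0.28 (exact permutation adjusted p = 0.0462, 1 of 6 tumours above every WT tumour; adjusted p = 0.274 with an estimated correlation). Of 18 members 17 had a positive fold change, 1 rose (Rrm2, a ribonucleotide reductase subunit), 0 fell and 17 did not pass over all genes, and 3 rose adjusted over the list alone. The edgeR Benjamini-Hochberg adjusted p of Rrm2 was 0.0291 (log2 fold change 0.62, 5 of 6 tumours), 0.062, 0.070 and 0.076 without WT 2, 4 and 6, 0.076, 0.064 and 0.074 without Alb-Cre Stat3f/f 1, 2 and 3, and 0.131 with the acinar score as a covariate (0.50 ± 0.15). With that covariate the list difference was 0.22 with a residual permutation adjusted p of 0.0713, and with members scaled to unit SD the exact permutation adjusted p was 0.0570. It was 0.0736, 0.0736, 0.0530, 0.0606 and 0.0866 by exact permutation without WT 1, 2, 3, 4 and 6 in turn. It was 0.0823, 0.0563, 0.0600, 0.0774 and 0.0733 by exact permutation without Alb-Cre Stat3f/f 1, 2, 3, 5 and 6.

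The other lists did not pass the exact permutation test of the mean over members. Among lists of other cells in the tissue, the score differed by 0.16 for fibroblast and matrix genes (adjusted p = 0.463, 1 of 6 tumours above every WT tumour) and by -0.11 for smooth muscle and pericytes (0.640, 1 of 6 below). The endothelial score differed by -0.01 (exact permutation adjusted p = 0.935, 1 of 6 below), where the median fold change of the members was 0.04. Single members were called all the same. Dcn, a matrix proteoglycan gene of fibroblasts, had a log2 fold change of 0.96 ± 0.22 (5 of 6 tumours above every WT tumour) and Flt1, an endothelial receptor for Vegfa, -0.36 ± 0.09 (6 of 6 below). The edgeR Benjamini-Hochberg adjusted p was 0.0337 for Dcn and 0.0423 for Flt1, and 0.0394 and 0.0478 with the acinar score as a covariate. Neither call was firm: by the same edgeR test with Benjamini-Hochberg adjustment Dcn had 0.0616 and Flt1 0.0506 without a filter. By that edgeR Benjamini-Hochberg test without the acinar-rich tumours Dcn had 0.201 (log2 fold change 0.77 ± 0.23) and Flt1 0.358 (-0.36 ± 0.15). Dcn lost its call without 7 of the 12 tumours in turn and Flt1 without 9. The acinar score differed by 2.39 (exact permutation adjusted p = 0.187, 4 of 6 above), and by 3.44 without Alb-Cre Stat3f/f 5, with an adjusted p of 0.0213. All 13 tested acinar genes had a positive fold change, and 0 passed over all genes or adjusted over the list alone. The islet score differed by 1.34 (exact permutation adjusted p = 0.182, 1 of 6 above; 0.0416 without WT 5), the adipocyte score by 0.35 (0.603, 2 of 6 above) and the hepatocyte score by -0.31 (0.690, 1 of 6 below). Among immune lists, B and plasma cell markers differed by 0.99 (exact permutation adjusted p = 0.182, 4 of 6 above; 0.0247 without Alb-Cre Stat3f/f 6) and neutrophil markers by 0.37 (0.182, 0 of 6 above; 0.0373 without WT 3). The neutrophil difference was 0.89 by the median over members, with an exact permutation adjusted p of 0.0154. Camera with the preset correlation passed the B and plasma cell, acinar and islet lists (adjusted p = 0.0347, 7.69e-07 and 0.00666). By the same exact permutation test mast cell markers differed by 0.28 (adjusted p = 0.603, 2 of 6 above) and inflammatory cytokines by 0.08 (0.690, 0 of 6 above). Of the 13 STAT3 target genes 1 rose, 0 fell and 12 did not pass over all genes, and 2 rose adjusted over the list alone. Il6ra, the interleukin 6 receptor, rose from 16.1 ± 3.02 to 26.6 ± 4.97 CPM (log2 fold change 0.72 ± 0.16, adjusted p = 0.0180 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 of 6 tumours). With the acinar score as a covariate its edgeR Benjamini-Hochberg adjusted p was 0.0965 (log2 fold change 0.61 ± 0.18). STAT3 target genes differed in score by 0.06 (exact permutation adjusted p = 0.658, 1 of 6 above), epithelial-mesenchymal transition genes by 0.07 (0.649, 0 of 6 above; 0.0416 by the median over members) and ribosomal protein genes by -0.02 (0.690, 1 of 6 below). Of the transition genes Tgfbi, a matrix protein, was called, with a log2 fold change of 0.65 ± 0.14 and an edgeR Benjamini-Hochberg adjusted p of 0.0177. Without WT 4 or Alb-Cre Stat3f/f 1 that edgeR Benjamini-Hochberg value was 0.0506 and 0.0552.

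The largest fold changes belonged to a pair of neighbouring genes on chromosome 11. BC018473, annotated as an antisense RNA gene (116752167 to 116759373, plus strand, GRCm38), had 3461 counts in Alb-Cre Stat3f/f and 2 in WT tumours, a ratio of 2149 (95% exact binomial interval 594.3 to 17748, counting error only). Each Alb-Cre Stat3f/f tumour held 435 to 762 counts of BC018473, or 95.5 ± 15.1 CPM. St6galnac1, a sialyltransferase gene (116765025 to 116775507, minus strand), had 196 and 3 counts, a ratio of 81.1 (27.4 to 396.7). All WT counts of both genes were in WT 6. Without it, and with the WT group set to 3 counts, BC018473 was 1207-fold and St6galnac1 68.4-fold higher in Alb-Cre Stat3f/f tumours. At the 0 WT counts then left, the lower limits of the 95% exact binomial interval were 981 and 55.1 (counting error only). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment BC018473 had an adjusted p of 5.83e-15 and St6galnac1 2.36e-05, each with 6 of 6 tumours above every WT tumour. The strand setting of the counting was not given in the sources used here, so the strand of these reads is open. Zbtb16, a transcription factor of innate-like lymphocytes that glucocorticoids also induce, rose from 9.74 ± 4.42 to 100.5 ± 58.0 CPM (log2 fold change 3.37 ± 0.48, adjusted p = 0.00586 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 of 6 tumours). With the acinar score as a covariate it rose by 2.83. Without the acinar-rich tumours its log2 fold change was 2.25 ± 0.44 with an edgeR Benjamini-Hochberg adjusted p of 0.0806. Of the 15 genes with the largest rise and the 15 with the largest fall, 6 and 5 were called with the acinar score as a covariate, and 4 and 2 without the acinar-rich tumours.

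**Figure D4:**
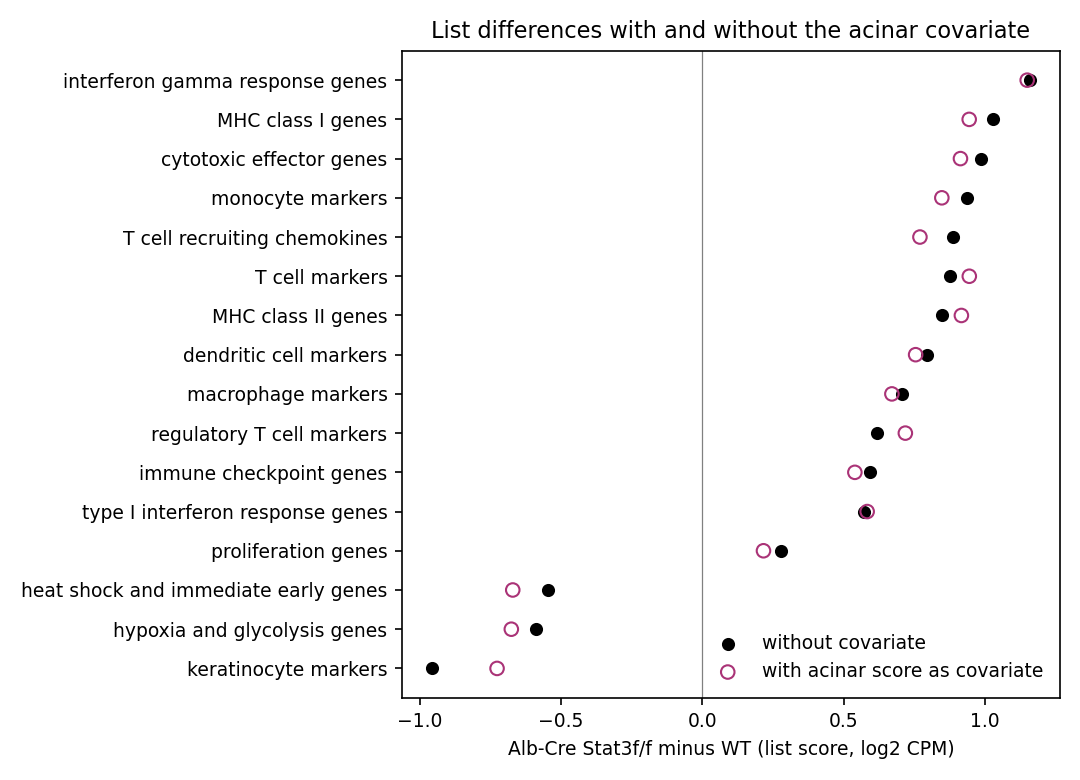
Points give the Alb-Cre Stat3f/f minus WT difference in list score (mean log2 CPM) without and with the acinar score as a covariate. The MHC class I difference was 1.03 and 0.94, and the hypoxia and glycolysis difference -0.59 and -0.68.

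T cell, dendritic cell and chemokine scores all differed between genotypes, so r over the 12 tumours carries the group difference and its p does not test a relation among tumours of 1 genotype. T cell and dendritic cell scores had Pearson r = 0.884 (permutation p = 0.00013, adjusted p = 0.00132 over 12 relations). Spearman rho was 0.881 (permutation p = 0.00038), and r was 0.812 without the 2 tumours farthest from the median dendritic score. Within WT tumours r was 0.881 (exact permutation p = 0.00556, adjusted p = 0.0222) and rho 0.943 (exact permutation p = 0.0167, adjusted p = 0.0667), with r = 0.674 without the 2 farthest. Within Alb-Cre Stat3f/f tumours the relation did not pass, with r = 0.362 (exact permutation p = 0.393, adjusted p = 0.590) and rho = 0.371 (exact permutation p = 0.497). There r was -0.357 without the 2 farthest, so its sign rested on them. Whether the relation differed between genotypes was not tested. T cell and chemokine scores had r = 0.866 over the 12 tumours (permutation p = 0.00022, adjusted p = 0.00132) and rho = 0.902 (permutation p = 0.00014), with r = 0.76 without the 2 farthest. A relation of T cell and chemokine scores apart from genotype was not shown, since neither genotype passed alone, with r = 0.648 in WT (exact permutation p = 0.144, adjusted p = 0.289) and r = 0.740 in Alb-Cre Stat3f/f tumours (exact permutation p = 0.0764, adjusted p = 0.229). Without the 2 farthest tumours these were -0.483 in WT and 0.622 in Alb-Cre Stat3f/f tumours. T cell scores had r = -0.494 with the ductal epithelial score (permutation p = 0.105, adjusted p = 0.252; rho = -0.490, permutation p = 0.111). They had r = 0.206 with library size (permutation p = 0.525, adjusted p = 0.699; rho = 0.0699, permutation p = 0.836). Within WT and within Alb-Cre Stat3f/f tumours r was -0.495 and -0.0129 for the epithelial score and -0.127 and -0.187 for library size.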

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

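The tests of acinar content and of a lower tumour cell share were chosen after the results they bear on had been seen. The tests of other splits and of handling before fixation were written beforehand. Those of a genetic difference between the hosts, of the genes around Stat3 on chromosome 11 and of acinar content for BC018473 were written before their own outcome. BC018473 was itself named from the fit, so the tests about it followed the pattern they bear on.

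Immune and antigen presentation genes were higher in tumours of Alb-Cre Stat3f/f hosts, and acinar content was higher in most of the same tumours; with an estimated correlation only the monocyte and MHC class I lists passed (adjusted p = 0.0426 for both). The tables argue against acinar content as the whole cause: with the acinar score as a covariate 91.9% of the MHC class I difference was left (residual permutation p = 0.0043). A lower share of tumour cells alone would raise macrophage and endothelial markers alike. The macrophage score rose by 0.72 more than the endothelial score (exact permutation p = 0.0022, the smallest possible). Both differences, 0.71 and -0.01, had been seen, so that p restates them and does not count as evidence. The fibroblast score, at 0.16, did not pass. These values argue against an even rise of all host cells only, and a lower share of tumour cells stays open. A score of 4 Y chromosome genes that was 1.04 higher may go with more host cells, but the sex of the hosts is not in the labels. Of 100 splits drawn from 462 only the real one gave as many as 383 calls, and the highest other drawn gave 74. This argues against an arbitrary grouping as their source. A split by acinar score, with 5 Alb-Cre Stat3f/f tumours among the 6 highest, gave 534 higher and 279 lower genes. That points to a structure of the samples beside the genotype. The drawn splits cannot exclude a chance overlap of acinar content with genotype as a source of part of the calls. The deletion of Stat3 in hepatocytes stays open as a biological explanation and was not itself tested, and so does a difference between the hosts that the labels do not give.

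Hypoxia and heat shock genes were lower in the same tumours, with adjusted p = 0.0867 and 0.183 with an estimated correlation, and the heat shock list lost its call without 9 of the 12 tumours in turn. The covariate fit argues against acinar content as the whole cause, since there the hypoxia difference was 114.9% of its size (residual permutation p = 0.0087). Without the acinar-rich tumours it was smaller, at -0.43 against -0.59 (exact permutation adjusted p = 0.349). With 2 Alb-Cre Stat3f/f tumours left, that setting cannot tell whether part of the fall goes with acinar content. A difference in ischaemia or handling before fixation may lie behind both lists and stays open: within a genotype their scores had r = 0.610 in WT (exact permutation p = 0.178) and r = 0.529 in Alb-Cre Stat3f/f tumours (p = 0.279), positive in both but past the threshold in neither. A lower share of tumour cells stays open too, since the difference in epithelial score minus that in hypoxia score was 0.45 (exact permutation p = 0.054) and the epithelial list itself passed as lower in 3 of the other tests; it and the pattern cannot be told apart with 6 tumours per group. A change of oxygen supply or tumour growth with the host genotype is a biological explanation that was not tested.

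BC018473 and St6galnac1, neighbours on chromosome 11, were almost silent in WT tumours and present in every Alb-Cre Stat3f/f tumour. A genetic difference between the hosts that host cells carry into the tumour stays open: 6 of 6 Alb-Cre Stat3f/f tumours had BC018473 above every WT tumour, which restates the pattern and does not test its source. Acinar content is argued against, since Alb-Cre Stat3f/f 5, with the lowest acinar score of its group, had 81.7 CPM of BC018473. Whether other genes near the floxed Stat3 locus, 15.8 Mb away, differ as a group stays open: 18 of 494 tested genes within 20 Mb were called against 361 of 12241 elsewhere, an odds ratio of 1.24 (95% interval 0.723 to 2.02, Fisher's exact p = 0.345). A mark of the strain or construct of these hosts and an effect of the deletion cannot be told apart, since the design sets both in the same 6 tumours.

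Single tumours stood apart from the others of their genotype in 11 of 152 groups of 6 values tested, where 7.6 are expected by chance. In Alb-Cre Stat3f/f 4 the regulatory T cell score was 2.70 (others 3.19 to 3.47), the dendritic cell score 3.39 (others 3.87 to 4.10) and Krt19 8.92 log2 CPM (others 9.09 to 9.17). In Alb-Cre Stat3f/f 6 the hepatocyte score was 1.01 (others 3.27 to 3.96) and Alb 2.32 log2 CPM (others 5.89 to 7.14). The acinar score was 7.54 in Alb-Cre Stat3f/f 5 (others 12.3 to 15.02), and Zc2hc1c was -0.0086 log2 CPM in Alb-Cre Stat3f/f 1 (others 1.36 to 1.52). Among WT tumours, the fibroblast and matrix score was 7.29 in WT 1 (others 6.70 to 6.85) and the islet score 5.39 in WT 5 (others 1.62 to 2.87). WT 6 had the only WT counts of BC018473 and St6galnac1, at -0.82 and -0.50 log2 CPM (others -1.79 for both). Outside the gene symbols, the 26 entries named by a date number held up to 0.166% of a library's counts (lowest 0.0690%).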

How the results depend on the processing

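The alternatives with the acinar score as a covariate, without the acinar genes and Rn45s and without the acinar-rich tumours were chosen after the data were seen. The direction of every called list and of all 65 called named genes held under each alternative that gave a value. RLE or upper quartile factors, no filter, a strict filter, edgeR without robust estimation, thinning and leaving out the acinar genes and Rn45s moved neither count by over 1.5 times. Higher and lower genes numbered 614 and 283 with DESeq2, 443 and 181 with voom, 156 and 48 with library size as a covariate, 82 and 13 with genes detected, 135 and 34 with the acinar score, and 83 and 14 without the acinar-rich tumours, with fewer samples; for the rest the cause was not tested. Leaving out each tumour gave 141 to 471 higher and 37 to 222 lower genes. With the replicate number as a block (replicate block) 145 and 44 genes passed and 0 lists did, since 64 sign flips give no p under 0.031; the T cell, cytotoxic and dendritic differences stayed at 0.88, 0.99 and 0.79 (exact sign-flip adjusted p = 0.0769). Same-numbered tumours had r of 0.127, -0.182, -0.0853, 0.107, -0.513 and 0.10 and 0 of 6 matched best with their own number, so the numbers were not taken as pairs. Camera with an estimated correlation passed 2 lists, with adjusted p = 0.101, 0.0920 and 0.0792 for the T cell, cytotoxic and dendritic lists; the cause was not tested. Without the acinar-rich tumours 0 lists passed, as 21 relabellings give no p under 0.048, and the same differences were 1.26, 1.33 and 1.02 (exact permutation adjusted p = 0.112). The hypoxia and glycolysis difference was smaller in that setting, at -0.43 (exact permutation adjusted p = 0.349). Leaving out each tumour, 13 to 17 lists passed. Under the strict filter 13 of the 16 called lists had a value and 12 of these kept their call. The T cell list was among those without a value. Leaving out mitochondrially encoded genes was not run, as no such gene was among the symbols. Among lists scored in the main test, those gained by the median over members were the neutrophil and epithelial-mesenchymal transition lists. The ductal epithelial list was gained with members scaled to unit SD, by fry and by camera with the preset correlation. That camera test also gained the B and plasma cell, acinar and islet lists. Without the low count filter 17 lists passed, the 16 called ones and another that had no score in the main test. Of the 65 called named genes, 21 passed without the acinar-rich tumours, 23 with genes detected as a covariate, 31 with the acinar score and 35 with the block. Depth limits Saa1, Gzmb, Ifng and Foxp3, which did not pass the low count filter of the main test and entered only the fit without a filter.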

Other observations

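Genes of alternatively activated macrophages, a list written after some of its members had been seen among the called genes, were higher in every Alb-Cre Stat3f/f tumour than in any WT tumour. All 8 tested members had a positive fold change and 5 rose over all genes (Retnla, Mrc1, Clec10a, Ccl24 and Ccl17). Clec10a, a lectin of macrophages and dendritic cells, rose from 15.5 ± 5.09 to 36.0 ± 6.79 CPM (SD, n = 6; log2 fold change 1.22 ± 0.19), and Ccl17, a chemokine for Ccr4, from 12.7 ± 3.61 to 27.5 ± 6.49 CPM (log2 fold change 1.12 ± 0.20). The adjusted p was 0.00176 for Clec10a and 0.00422 for Ccl17 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Clec10a and Ccl17 kept their call without any 1 tumour. The edgeR Benjamini-Hochberg adjusted p was 0.0518 to 0.102 for Retnla without any 1 tumour but Alb-Cre Stat3f/f 5, 0.0629 to 0.0995 for Mrc1 without WT 1, 2, 3, 4 or 6 or Alb-Cre Stat3f/f 1, 2 or 6, and 0.0552 to 0.0650 for Ccl24 without WT 1, 3, 4 or 6 or Alb-Cre Stat3f/f 1, 3 or 6. With the acinar score as a covariate Clec10a and Ccl17 kept their call, while Retnla, Mrc1 and Ccl24 had edgeR Benjamini-Hochberg adjusted p-values of 0.118, 0.206 and 0.0679 at log2 fold changes of 1.79, 0.57 and 1.81, against 2.22, 0.72 and 1.90. Ccl24 and Ccl17 passed that edgeR test without the acinar-rich tumours (Benjamini-Hochberg adjusted p = 0.0103 and 0.0224, log2 fold changes 2.82 and 1.25), and Clec10a, Mrc1 and Retnla did not (0.0501, 0.0998 and 0.453 at 1.30, 0.56 and 1.97). The score differed by 1.11 (exact permutation p = 0.0022), and by 0.97 with the acinar covariate (residual permutation p = 0.0043). Since members were chosen for their rise, neither p counts as evidence.

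Glucocorticoid response genes and Y chromosome genes were 2 more lists chosen after the data had been seen. Of 12 glucocorticoid response genes 11 had a positive fold change and 0 passed over all genes. Nearest were Per1, a clock gene, and Tsc22d3, a leucine zipper gene, with log2 fold changes of 0.90 ± 0.24 and 0.49 ± 0.14 and edgeR Benjamini-Hochberg adjusted p-values of 0.0527 and 0.0629. Per1 passed that edgeR Benjamini-Hochberg test without WT 6 (0.0432) or Alb-Cre Stat3f/f 1, 5 or 6 (0.0422, 0.0464 and 0.0447), Tsc22d3 without Alb-Cre Stat3f/f 1 (0.0452), and Mt1 and Mt2 without Alb-Cre Stat3f/f 5 (0.0168 and 0.0201). Of the 12 genes 0 passed with the acinar score as a covariate or without the acinar-rich tumours. Their score differed by 0.68 (exact permutation p = 0.0173) and by 0.43 with the acinar covariate, where it did not pass (residual permutation p = 0.0779). Of 4 Y chromosome genes, all with a positive fold change, 3 rose over all genes, with log2 fold changes of 0.95 for Ddx3y, 1.27 for Eif2s3y and 1.34 for Uty, while Kdm5d had 0.77. The edgeR Benjamini-Hochberg adjusted p of Ddx3y, Eif2s3y and Uty was 0.0125, 0.0172 and 0.0143, that of Eif2s3y was 0.0527 without Alb-Cre Stat3f/f 1, and with the acinar score as a covariate the values were 0.0548, 0.0648 and 0.143 at log2 fold changes of 0.63, 1.15 and 0.94. Of the 4 genes 0 passed without the acinar-rich tumours. Their score differed by 1.04 (exact permutation p = 0.0022) and by 0.79 with the acinar score as a covariate (residual permutation p = 0.0022). As for the lists before it, members were named after their values were seen, so these p-values do not count as evidence.

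Saa1 and Saa2 were low against Alb in Alb-Cre Stat3f/f tumours, in a test chosen after their counts had been seen. The log2 ratio of Saa1 plus Saa2 to Alb counts, with 1 added to each, was -2.93 ± 0.84 in WT and -5.51 ± 1.69 in Alb-Cre Stat3f/f tumours (SD, n = 6), a difference of -2.58 (exact permutation p = 0.0065, 5 of 6 tumours below every WT tumour). The difference was -2.18 to -3.02 without any 1 tumour. A candidate explanation is that the tumours carry traces of liver-derived RNA, and that in Alb-Cre Stat3f/f hosts it comes from hepatocytes without Stat3, which drives Saa1 and Saa2. This stays open, since the counts had been seen and the test restates them, and they are few, at 429 in WT and 52 in Alb-Cre Stat3f/f tumours. Orm1, Orm2, Apcs and Itih4, other acute phase genes of the liver, were not low against Alb: the same ratio for their summed counts differed by 0.90 (exact permutation p = 0.299). The labels do not say how liver RNA could reach the sections.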
